A study of Mus musculus with 3 samples.

How the data were processed

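Total RNA from hippocampal area CA1 of mice was hybridised to 3 arrays, one per sample, and the labels place all 3 in one group, 2 h after training with context and shock. One table of values was used, with a row for each of 12488 probe sets. The probe set names, with 66 control probe sets, are those of an Affymetrix mouse array on which short oligonucleotides near the 3′ end of a transcript are read together as one probe set. The values deposited by the authors are signal intensities on a linear scale, from 0.8 to 83456. The software, background correction and summary method are not given in the sources used here. The mean after leaving out the lowest and highest 2% of probe sets was 499.9 on each of the 3 arrays, so the deposited intensities had been scaled to a common target. No detection calls or scanner files were used here.

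Gene names came from a platform annotation, which listed 11251 probe sets, 10855 of them with 1 gene symbol and 396 with several. Another 1237 probe sets were not listed and stayed unnamed. Symbols were looked up by gene identifier in a RefSeq gene table for GRCm38.p6; 10839 identifiers matched and no symbol had to be changed. Probe sets with several symbols named no gene. Arc, Nfkb1 and Ddx3y were not measured by any probe set with 1 symbol. The array values come with no genome build, so no coordinates are given.

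The array medians differed by 0.11 on the log2 scale, above the limit of 0.1 set for using the deposited scale, so the arrays were quantile normalised. Values under 50.9, the 25th percentile of all normalised values, were then set to that floor and log2 was taken. A value at the floor has no order, and a fold against it is a lower bound. The signals printed are normalised and not floored, while control ratios use the deposited intensities. A gene's signal is the mean over its probe sets, and its log2 value the mean of their log2 values; 2073 of 8251 genes had several. Background was the 90th percentile, 243, of the mean signals of 81 probe sets for genes of other organs, whose median was 49.9, and a gene was above it if any of its probe sets was. Spread between replicates was described on probe sets above 182.5, the median of all mean signals, and on genes above background.

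There was no second group, so no test between groups could be made and no paired design exists. For 25 gene lists, the median SD of log2 signal and the median deviation of each replicate from the gene means were set against 10000 random lists of the same size, drawn within 20 bins of mean log2 signal. Lists with under 5 genes above background (dentate gyrus, blood cell and sex-linked genes) were not ranked. Agreement of probe sets of one gene was measured as the pooled correlation of their deviations and tested by 10000 random re-pairings within bins of signal. The procedure was tested on simulated data built from the 4331 genes above background, with noise independent between genes. Of 100 unshifted random lists of 25 genes, 1 was called apart, as were 4 of 4 lists shifted by 0.4 and 4 of 4 shifted by 0.8 on the log2 scale in one replicate. These counts do not give the rate of false calls for lists whose genes vary together. For the probe set pairs of 681 genes, a simulated shared share of 0.5 was recovered as 0.504. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

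The lists, the scaling rule, the floor, the background limit and the rule for named genes were fixed before the data were examined. The rule took, per list, the 3 genes of highest mean signal and the 1 with the largest SD among those above background, the 12 genes with the largest range, and a short set of genes chosen for the question, such as Fos, Egr1, Bdnf, Rel, Wfs1, Prox1 and Ttr; summarised lists are given with fewer names. Fosb, Syt1, Syt11, Syp, Cplx1, Napb, Vamp2, Gphn, Mal, Mag, Kdm5d, Eif2s3y, Uty and the channel and kinesin genes of the closing observations other than Kif5c fall outside the rule and were named after their values were seen. The alternatives were median scaling, the deposited scale, floors at the 10th and 40th percentiles, no filter on low signal, the brightest probe set per gene, other background limits, pairs without shared-probe suffixes and leaving out each replicate in turn.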

Results

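The series held 3 oligonucleotide arrays of total RNA from area CA1 of the hippocampus, a region required for memory of a place, taken from young male C57BL/6J mice after contextual fear conditioning. In this training a mouse learns to associate a new chamber with a mild foot shock. The mice spent 2 min in the chamber before each of 3 shocks of 0.5 mA that lasted 1 s, returned to the home cage 1 min after the last one, and RNA was collected 2 h after it. All 3 samples belong to this one group and are called replicates 1, 2 and 3 after their labels. The labels do not say whether they came from separate animals or pools, so the spread between them may be partly technical. No untrained or context-only sample was analysed here, so the data give the level of each transcript after training and its spread between replicates, and no change caused by training. Each array gave a signal for 12488 probe sets, and the median signal was 186.6, 172.5 and 186.8 on replicates 1, 2 and 3. With 3 arrays, the number of replicates limits the precision of every value.

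The transcripts of learning-related and neuronal genes were measured first for presence. A probe set counted as above background when its mean signal over the 3 arrays was above 243, and a gene when any of its probe sets did, so that a gene's mean signal can lie below this limit. The limit is the level that 90% of 81 probe sets for genes typical of liver, testis, muscle, lens and other organs did not exceed. Of 8251 genes measured, 4331 were above background. The numbers below are signal on the common array scale, as mean ± SD (n = 3 arrays). They depend on the probe sequences, so one gene's signal is not set against another's.

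Immediate early genes, which neurons transcribe within minutes to hours of activity, were above background in 23 of 42 measured cases. Among them, Egr1, a zinc finger transcription factor, had a signal of 1314 ± 260.4, Nr4a1, a nuclear receptor, had 621 ± 29.9 and Fosb, a partner of Jun proteins, had 765 ± 61.6. The Egr1 value averages 1 probe set at 2569 and another at 59.55, below background. Plk2 and Plk3, polo-like kinases, had 8158 ± 854 and 5851 ± 920.5, and Jund had 15712 ± 3778. Bdnf, the brain-derived neurotrophic factor, had 2114 ± 166 with a range of 1.15-fold between replicates. Fos, at 231 ± 56.8, had 1 of its 2 probe sets above background. Homer1, a postsynaptic scaffold gene, stayed below background at 115 ± 29.7. With a lower limit of 77.7, taken from bacterial control probe sets, 38 of the 42 genes counted as above background. The median deviation of the group from the gene means was 0.07, 0.02 and -0.06 on the log2 scale in replicates 1, 2 and 3, and the range of these values lay at the 57.55th percentile of 10000 random gene lists of the same size and signal. Junb had the largest spread, and its 2 probe sets did not move together. One read 55.6, 459.6 and 222 in replicates 1, 2 and 3, and the other 456, 387 and 749.8.

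Of the NF-kappaB transcription factors and their regulators, 8 of 19 measured genes were above background. Rela, which encodes the p65 subunit, had a signal of 512 ± 16.7, with one of its 2 probe sets at the floor on all 3 arrays. The inhibitors Nfkbia and Nfkbib had 564 ± 71.7 and 682 ± 87.9. Rel, which encodes c-Rel, was at the floor on all 3 arrays, with 47.4, 46.4 and 21.8, so no level can be given for it. With the lower limit of 77.7, 15 of the 19 genes counted as above background. Relb had the largest spread of the group, at 202, 199 and 117 in replicates 1, 2 and 3. These values average 1 probe set at 285, 357 and 198 and another at 120, 41.6 and 34.8. The latter was below background, and at the floor in replicates 2 and 3. The median deviation of the group was -0.05, 0.10 and -0.04 in the 3 replicates, at the 38.4th percentile of random lists.

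Kinases, phosphatases and transcription factors of the CREB, PKA, PKC, CaMK and ERK pathways were above background in 22 of 30 cases. The calcineurin subunit Ppp3r1 had 13161 ± 1613, the PKA subunit Prkar1a had 11445 ± 1016 and the PKC gene Prkcb had 9174 ± 894. Prkar1b, a further PKA subunit, had the largest spread, at 2542, 4360.3 and 5351 in replicates 1, 2 and 3. Creb1, at 81.4 ± 10.9, was below background. Histone and DNA modifying enzymes were above background in 21 of 28 cases, among them the deacetylase Hdac5 at 2282 ± 365 and the nucleosome-binding protein gene Hmgn1 at 3634 ± 510.4. Kat2a, a histone acetyltransferase, read 561, 102 and 511. Genes that respond to glucocorticoids were above background in 16 of 21 cases. The metallothionein genes Mt1 and Mt2 had 12133 ± 1849 and 16573 ± 2277, the receptor co-chaperone gene Fkbp5 had 1119 ± 236, and the kinase gene Sgk1 had 900.3 ± 381, with 916, 1273 and 512 in replicates 1, 2 and 3. The ranges of the shifts of these 3 groups lay at the 59.0th, 94.7th and 80.7th percentiles of random lists. Heat shock proteins and chaperones were above background in 30 of 33 cases, with Hsp90aa1 at 8885 ± 290.5 and Hspa8 at 6563 ± 1069, and their range lay at the 93.6th percentile. The Hsp90aa1 value averages 1 probe set at 17736 and another at 34.55, below background.

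Marker genes of the cell types that the tissue could hold were described next. Markers of pyramidal cells and CA1 were above background in 14 of 16 cases, including Wfs1, a marker of CA1 pyramidal cells, at 2051 ± 192, and Hpca, which encodes the calcium sensor hippocalcin, at 15595 ± 3452. Dentate gyrus markers were above background in 4 of 13 cases. Prox1, the granule cell transcription factor gene, was at the floor in replicates 1 and 3 and had a signal of 93.1 in replicate 2. Calb1, of the same list, had a mean signal of 1658. Markers of CA3 and CA2 were above background in 6 of 11 cases, with Rgs14, a CA2 marker, at 4369 ± 129. Interneuron markers were above background in 12 of 22 cases, including Gad1, which encodes an enzyme of GABA synthesis, at 3839.5 ± 344 and the neuropeptide genes Sst and Cck at 10156 ± 1143 and 15220.2 ± 1892. Astrocyte markers were above background in 19 of 21 cases, with Gfap at 997 ± 144, and oligodendrocyte lineage markers in 15 of 17, with Mbp, a myelin protein gene, at 4321 ± 770.5. Microglia and macrophage markers were above background in 13 of 26 cases, with Ctss at 2557 ± 506 and C1qc at 1571 ± 293. Endothelial and mural markers were above background in 11 of 27 cases, choroid plexus and meningeal markers in 7 of 24, thalamic and cortical markers in 7 of 16 and blood cell genes in 3 of 12. Ttr, the transthyretin gene of the choroid plexus, was below background at 207 ± 40.6, and the haemoglobin gene Hba-a1 had 2395 ± 388. Dcn, of the choroid plexus and meningeal list, had a mean signal of 2664, and Fezf2, of the thalamic and cortical list, 1812. Of the organ-specific genes used to set the background, 8 of 63 exceeded it by construction of the limit. Xist, the transcript of the inactive X chromosome, was at the floor on all 3 arrays, with 9.03, 48.3 and 43.0. Of the Y-linked genes, Kdm5d was at the floor on all 3, and Eif2s3y and Uty had 173 ± 32.1 and 111 ± 42.9, below background.

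Agreement between the 3 samples was compared next. Replicates 2 and 3 were closest, with a Pearson correlation of log2 signal of 0.961 and a Spearman correlation of 0.946 across 6211 probe sets of above-median signal. Replicate 1 correlated with replicate 2 at 0.915 and 0.899, and with replicate 3 at 0.894 and 0.874. These correlations run across probe sets, which are not independent replicates. The median SD of log2 signal over the 3 arrays was 0.26, and 899 probe sets, or 14.5%, had a range over 2-fold. Without replicate 1, the count was 187. In 602 of the 899 probe sets, replicate 1 lay farthest from the other 2, lower in 444 and higher in 158. No pair of arrays held the same values.

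The control probe sets along single transcripts differed in the same replicate. For Gapdh, a glycolytic enzyme gene, the ratio of the 3′ to the 5′ probe set was 7.11 in replicate 1, 1.29 in replicate 2 and 1.07 in replicate 3. For Actb, which encodes beta-actin, it was 3.58, 2.24 and 1.70. The 5′ Gapdh signal was 4842 in replicate 1 against 27696 and 31263 in replicates 2 and 3, while the 3′ signal was 34444, 35786 and 33497. Bacterial transcripts of the hybridisation controls differed less: over 8 probe sets, the highest signal exceeded the lowest by 1.16-fold in the median and by 1.43-fold at most.

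**Figure D1:**
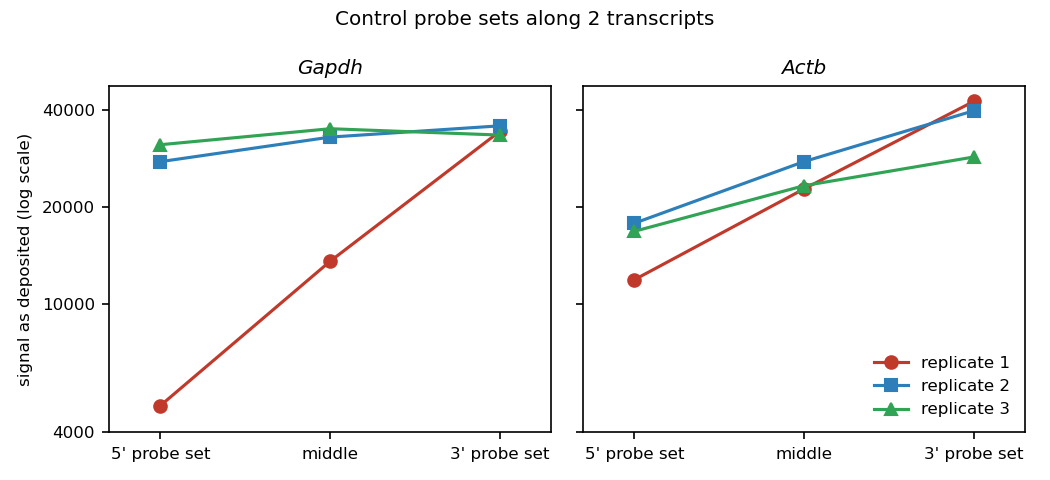
Deposited signal (vertical axis, log scale, arbitrary units) of the control probe sets at the 5′ end, the middle and the 3′ end of Gapdh and Actb (horizontal axis), one line per replicate. The 5′ Gapdh signal of replicate 1 was 4842, below the 27696 and 31263 of replicates 2 and 3, while the 3′ signals of the 3 replicates lay between 33497 and 35786.

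Synaptic genes were lower in replicate 1 than in the other 2 samples. Of 22 gene lists with enough members to rank, 3 stood apart from random lists of the same size and signal. They were presynaptic and vesicle genes, GABA receptors with their associated proteins, and glutamate receptors with postsynaptic genes. With genes that varied independently, 0.22 lists would stand apart, a number that does not hold for genes that vary together. A list stood apart when the range of its 3 median deviations reached the 99th percentile of 10000 random lists. All 3 lists were also lowest in replicate 1 with median scaling, at -0.60, -0.48 and -0.32 in the order named, and on the deposited scale, at -0.57, -0.45 and -0.28. In the same replicate, pyramidal cell markers had a median deviation of -0.25, astrocyte markers of 0.13 and microglial markers of 0.12, at the 0.43th, 92.7th and 86.4th percentiles of random lists. With median scaling these values were -0.29, 0.05 and 0.06, and on the deposited scale -0.25, 0.09 and 0.10. Interneuron, endothelial and oligodendrocyte markers had 0.04, 0.01 and -0.08, and the endothelial value was -0.02 with median scaling. Members of a list were mixed in replicate 1. Of 14 pyramidal cell markers, 5 were above their mean there, Wfs1 at 0.03 among them. Below their mean were 6 of 19 astrocyte markers, among them Aldoc, and 5 of 13 microglial markers, among them C1qc. Genes of one list are not independent, so these percentiles describe the 3 arrays and are not p-values.

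Presynaptic and vesicle genes had a median deviation of -0.66 in replicate 1, 0.11 in replicate 2 and 0.26 in replicate 3 on the log2 scale. Their range of 0.92 exceeded all 10000 random lists, whose median range was 0.10. Of the 25 genes above background, 11 were over 2-fold lower in replicate 1 than the mean of the other 2, none was over 2-fold higher and 14 were within 2-fold. Over all 4331 genes above background, 202 (4.7%) were over 2-fold lower in replicate 1 and 43 (1.0%) over 2-fold higher. Among the 11, Rab3b, a small GTPase gene of vesicle release, read 109, 736 and 559.5 in replicates 1, 2 and 3. Syt11 and Syt1, of the synaptotagmin family, read 605, 2303 and 3192, and 845, 1862 and 2836. Syp, the synaptic vesicle protein gene synaptophysin, read 595, 1637 and 1802. Other genes of the list did not share this difference. Snap25, which encodes a core protein of vesicle fusion, had 19411 ± 720.4 and a range of 1.08-fold, and Dnm1, a gene of vesicle recycling, read 24865, 21278 and 17427. In all, 9 of the 25 genes were above their own mean in replicate 1. Probe sets of one gene also differed. For Vamp2, which encodes a vesicle fusion protein, one read 133, 586 and 774 in replicates 1, 2 and 3 and the other 9582, 12527 and 13134. For Napb, one read 356, 1604 and 1334 and the other 2027, 2101 and 2005. The list also had a high spread, with a median SD of 0.57 over the 3 replicates against 0.21 in random lists. The 3′ to 5′ ratio of Gapdh was highest in replicate 1, at 7.11. Without replicate 1, the range of the list was 0.14, at the 98.1th percentile, and it no longer stood apart by shift, while its median SD, 0.26 between replicates 2 and 3, still exceeded all random lists.

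**Figure D2:**
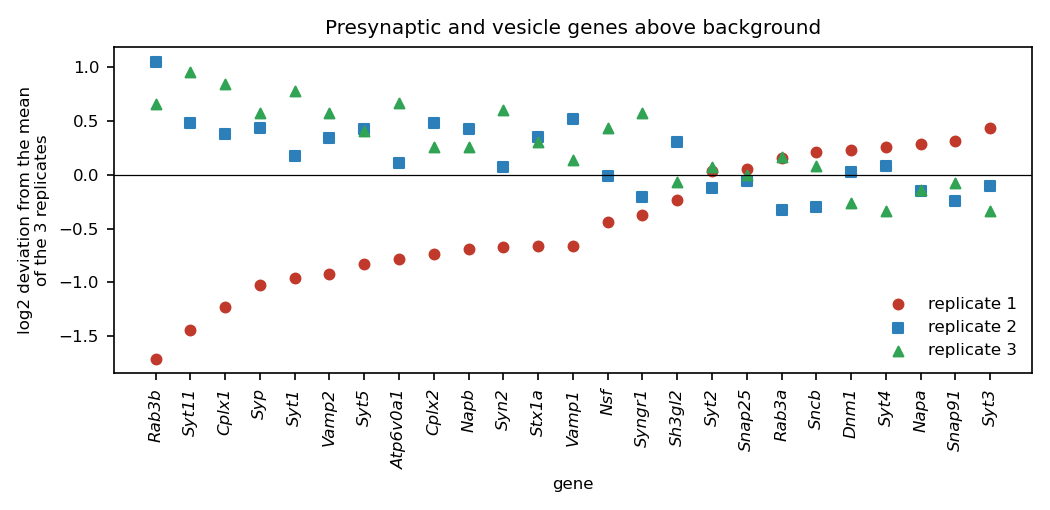
Deviation of log2 signal from the gene's mean over the 3 replicates (vertical axis) for the 25 presynaptic and vesicle genes above background (horizontal axis, sorted by replicate 1), one marker per replicate. Replicate 1 was lowest for Rab3b, Syt11 and Cplx1, and 9 genes at the right, Snap25 and Dnm1 among them, were above their mean in replicate 1.

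Glutamate receptors and postsynaptic genes had median deviations of -0.26, 0.19 and 0.17 in the 3 replicates, with a range at the 99.4th percentile. Of 13 genes above background, 12 were below their mean in replicate 1. Gria1, an AMPA receptor subunit gene, read 2094, 4233 and 4383, and both of its probe sets were lowest in replicate 1. Gria2, a further subunit gene, read 2468, 3450 and 3473 as the mean of 4 probe sets. Of those above background, 1 was highest in replicate 1, at 1187, 1048 and 1015. Nrgn, which encodes the calmodulin-binding protein neurogranin, read 3068, 4492 and 4434. Grin2b, an NMDA receptor subunit gene, was at the floor in replicate 1 and read 284 and 709 in replicates 2 and 3. The 5 GABA list genes above background had median deviations of -0.46, 0.10 and 0.36, at the 99.7th percentile. With 5 genes, these medians are the values of Gabbr1 alone. The receptor subunit genes Gabra2 and Gabbr1 read 284, 719 and 1129, and 3454, 5106 and 6089. Gabarap, which encodes a receptor-associated protein also used in autophagy, read 845, 2716 and 2523. Gabrb1 differed by 1.10-fold over the 3 replicates, and Gphn read 870, 669 and 743, highest in replicate 1. Without replicate 1, neither list stood apart, with ranges of 0.02 and 0.15 at the 21.4th and 83.4th percentiles. Pyramidal cell markers had deviations of -0.25, 0.09 and 0.11, at the 98.35th percentile, short of the limit. With median scaling of the arrays they reached the 99.35th percentile.

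**Figure D3:**
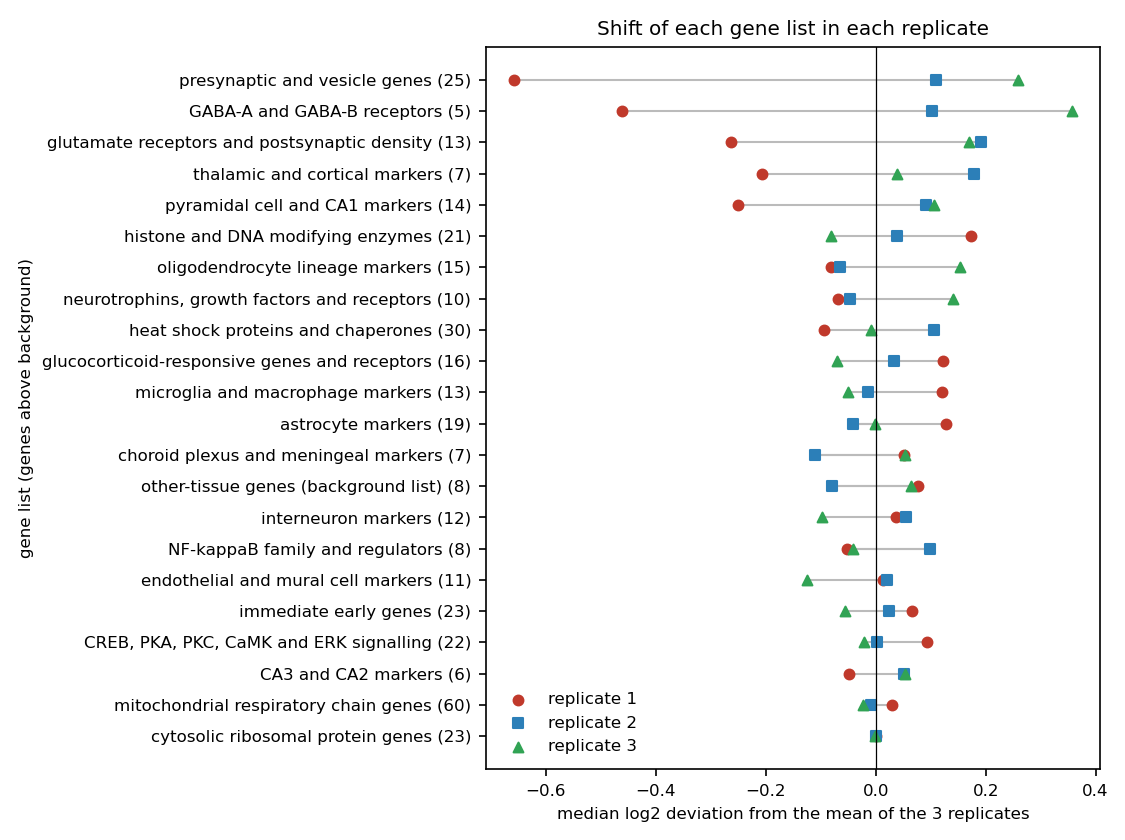
Median log2 deviation from the mean of the 3 replicates (horizontal axis) for each of the 22 ranked gene lists (vertical axis, with the number of genes above background), one marker per replicate. Presynaptic and vesicle genes lay at -0.66, 0.11 and 0.26 in replicates 1, 2 and 3, and the mitochondrial respiratory chain genes at 0.03, -0.01 and -0.02.

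Housekeeping groups and glial markers differed less than the synaptic lists over the 3 replicates, but oligodendrocyte markers stood apart between replicates 2 and 3. The 60 mitochondrial respiratory chain genes above background, of 72 measured, had a median SD of 0.15 on the log2 scale, at the 1.0th percentile of random lists, and none differed by over 2-fold between replicate 1 and the mean of the others. The range of their shifts lay at the 33.7th percentile. The 23 cytosolic ribosomal protein genes above background, of 31 measured, had a median SD of 0.14, at the 5.5th percentile. Astrocyte, microglial and endothelial markers had ranges at the 79.2th, 65.3th and 44.2th percentiles, interneuron markers at the 55.8th, choroid plexus and meningeal markers at the 42.7th, and CA3 and CA2 markers at the 18.4th. Neurotrophins, growth factors and their receptors, 10 of 20 of them above background, lay at the 68.2th percentile, and the organ-specific genes above background at the 38.5th. Oligodendrocyte markers had deviations of -0.08, -0.07 and 0.15, at the 86.7th percentile over the 3 replicates. Between replicates 2 and 3 alone, 12 of 14 oligodendrocyte genes were higher in replicate 3, with a median difference of 0.34, above all 10000 random lists. Over the 15 genes above background on 3 arrays, the median difference was 0.33, and it was 0.24 with median scaling and 0.35 on the deposited scale. Mal read 1949 and 2839, Mag read 460.2 and 791 and Mobp, at the mean of 4 probe sets, 4671 and 6212 in replicates 2 and 3, all genes of the myelin sheath. The thalamic and cortical list had a high spread, with a median SD of 0.57 over 7 genes at the 99.4th percentile, and no shift that stood apart, with a range at the 84.4th percentile. The spread reached the limit with all 3 scalings but not with either other floor, without the filter on low signal, with the brightest probe set or in any setting that left out a replicate. With the floor at the 40th percentile the median SD was 0.24, at the 57.8th percentile. With 7 genes, the median SD of 0.57 is the value of Cux1 alone, which has 2 probe sets. One read 925, 561 and 622 in replicates 1, 2 and 3. The other read 141, 215 and 48.1, below background and at the floor in replicate 3.

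The genes with the largest range of all were lowest in replicate 1. Among probe sets of above-median signal, the 12 genes with the largest range had their lowest value in replicate 1 in 12 of 12 cases. All 12 signals in replicate 1 were below the background limit of 243, so no fold is given for them and their order is not exact. Ksr1, which encodes a scaffold of the ERK pathway, read 669.5 and 856 in replicates 2 and 3 and was at the floor in replicate 1, as were Rex1bd, Rnf112, Grin2b and Kif5c. Rex1bd read 839 and 603 in replicates 2 and 3, Rnf112 read 439 and 613, and Kif5c, a neuronal kinesin motor gene, read 271 and 561. Lin7b, a synaptic scaffold gene, read 66.2, 860.4 and 897 in replicates 1, 2 and 3. Nfe2l1, a transcription factor gene, read 67.4, 434 and 902, and Ywhag, a 14-3-3 protein gene, read 93.3, 499.7 and 884. Kif5a, a further kinesin motor gene, read 200.2, 1066 and 2492. Rasgrp1, a Ras activator gene, Nbl1, a secreted BMP antagonist gene, and Tpgs1 read 65.1, 72.5 and 70.4 in replicate 1 and between 469.8 and 911 in the other 2. A second probe set above background did not share the difference in Ywhag. In Nfe2l1 it had the same order of replicates at a smaller range, 1.36-fold. The other Ywhag probe set read 19620.4, 15556 and 14531 in replicates 1, 2 and 3, and the other Nfe2l1 probe set 1914, 2179 and 2598.

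Over all genes with several probe sets of above-median signal, deviations between replicates were shared only weakly by the probe sets of one gene. The pooled correlation over 867 pairs from 681 genes was 0.085, against a median of 0.007 for random re-pairings (one-sided permutation test, p = 0.0022). With pairs limited to probe sets whose names do not mark shared probes, it was 0.111 over 283 pairs (one-sided permutation test, p = 0.0072). Without the filter on low signal it was 0.0276 over 3311 pairs (one-sided permutation test, p = 0.037), and without replicate 1 it was 0.067 (one-sided permutation test, p = 0.064).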

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

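Most results kept their side of the limits under the alternatives, and the exceptions follow. No paired analysis was possible because the series holds one group, so that no replicate number is shared between groups. The count of 3 lists that stood apart by shift was 3 or 4 with every scaling, floor, filter and probe set rule tried, and the 3 synaptic lists reached the limit in each of these. Leaving out single replicates gave 1 to 4 lists. These results depend on replicate 1: without it, the 1 list was that of oligodendrocyte markers, and the ranges of the synaptic lists fell short of the limit. Over the 3 runs without a replicate, the shift range was 0.14 to 0.94 for presynaptic genes, 0.0224 to 0.53 for glutamate receptors and 0.15 to 0.82 for the GABA list, lowest without replicate 1 in each. Over the same runs the mean Pearson correlation was 0.894 to 0.961, the median SD 0.153 to 0.257, the count of probe sets with a range over 2-fold 187 to 680 (899 with all 3) and the pooled correlation of same-gene probe sets 0.067 to 0.122, the value of 0.067 no longer past the threshold. Without the filter on low signal the pooled correlation was 0.0276. For a single probe set, a range over 2 arrays cannot exceed that over 3 at the same floor, which lowers the counts over 2-fold. This does not hold for the shift ranges of lists. Without replicate 2 they were 0.94 for presynaptic genes and 0.53 for glutamate receptors, against 0.92 and 0.45 with all 3. Without the filter on low signal, 2553 of 12422 probe sets had a range over 2-fold, since dim probe sets are included. The number of lists with a high spread was 1 rather than 2 with the floor at the 10th or the 40th percentile, without the filter and with the brightest probe set. The list lost was the thalamic and cortical one. Its median SD as reported was the value of Cux1 alone, which has 1 probe set below background and at the floor in replicate 3. How far this gene accounts for the loss in each setting was not tested. The number of lists with a low spread was 0, and it was 1 with median scaling and with the deposited scale, through the mitochondrial genes, and 2 without the filter, with the ribosomal genes added. The background limit set the number of genes above background, which was 4331, 4864 with the median of all signals and 6329 with the bacterial controls. Among single genes and lists outside these counts, 1361 values stayed as reported, 179 moved by more than their spread or, for counts, by over 1.5 times, 11 came to pass the limit and 9 ceased to. Signals near or below 243 cannot be told from those of genes of other organs, which limits Homer1, Creb1, Rel and Prox1.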

Other observations

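Of the tests below, that of scaling was set out before its result was seen, and those of noise, of neuron share, of the further gene families and of dimmer against brighter probe sets in their present order after the data had been examined. No biological explanation was tested, as the design names no difference between the replicates.

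Of 14 further gene families, named by the start of their symbols, 1 stood apart from random lists. The 9 sodium and calcium channel subunit genes above background had median deviations of -0.32, 0.06 and 0.26 in replicates 1, 2 and 3, at the 99.5th percentile of random lists. Cacng2 is among the 9 and also in the glutamate receptor list, so the family is not wholly separate from that list. Of the 9 family genes, 8 were below their mean in replicate 1. The range was 0.58, and it was 0.60 with median scaling and 0.61 on the deposited scale, at the 99.5th and 99.8th percentiles, and 0.26 over 18 genes without the filter, at the 99.1th. It was 0.56 without replicate 2, at the 99.3th percentile, and fell short of the limit without replicate 3, at 0.42 and the 98.55th, and without replicate 1, at 0.07 and the 46.3th. Replicate 1 also had the highest 3′ to 5′ ratio of Gapdh, 7.11 against 1.29 and 1.07, with pyramidal cell markers at -0.25 and astrocyte markers at 0.13, and whether the family shares a technical cause with these was not tested. Cacna1a, which encodes the pore of P/Q-type calcium channels, read 116, 402 and 312, Cacna1b read 411, 535 and 613, and the sodium channel gene Scn8a read 137, 549.7 and 606. Kinesins did not stand apart as a family, at the 43.9th percentile, although 3 of 9 were over 2-fold lower in replicate 1. Kif1a, a motor gene of vesicle transport, read 316, 584 and 1491, while Kif5b differed by 1.08-fold over the 3 replicates. Proteasome subunits (38 genes), zinc finger proteins (40 genes) and RNA splicing factors (34 genes) lay at the 72.9th, 2.65th and 43.7th percentiles. The remaining families lay between the 8.0th percentile, for translation initiation factors, and the 87.8th, for G protein alpha subunits.

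Signal lost away from the 3′ end of transcripts in replicate 1, the array with the highest 3′ to 5′ ratios, was weighed as a source of the weak agreement between probe sets of one gene. Leaving out replicate 1 did not raise the pooled correlation, which was 0.067 against 0.085 with all 3 arrays. It was 0.104 without replicate 2 and 0.122 without replicate 3. These values do not decide the question, since less variation was left for probe sets to share without replicate 1. The SD of log2 differences was 0.41 between replicates 2 and 3. It was 0.62 and 0.69 between replicate 1 and replicates 2 and 3. With the probe sets of a gene ordered by replicates 2 and 3 alone, the mean of dimmer minus brighter over 554 genes was -0.0565 ± 0.0260 (SE) on the log2 scale in replicate 1 (one-sided sign-flip permutation test, p = 0.0152). Ordered by all 3 replicates, which favours a negative mean, it was -0.0716. The dimmer probe set was lower in 280 of the 554 genes, so the mean rests on a part of them, and larger noise of dim probe sets in that array and the distance of each probe set from the 3′ end were not tested. Independent noise of each probe set alone is argued against by the pooled correlation of 0.085, above the upper limit set for random re-pairings, 0.061, but only weakly, since it was 0.0276 without the filter on low signal (one-sided permutation test, p = 0.037) and 0.067 without replicate 1 (p = 0.064).

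The lower signal of presynaptic and vesicle genes in replicate 1 was weighed against 3 technical accounts. The scaling between arrays is argued against as the whole cause, since the range was 0.825 with median scaling and 0.827 on the deposited scale, above all random lists in both. A lower share of neurons cannot be told apart: in replicate 1 pyramidal cell markers lay at -0.25, glutamate receptor genes at -0.26, and astrocyte and microglial markers at 0.13 and 0.12 (0.05 and 0.06 with median scaling), but oligodendrocyte markers lay at -0.08, endothelial markers at 0.01 and interneuron markers at 0.04. In replicate 1, 5 of 14 pyramidal cell markers were above their mean, and 6 of 19 astrocyte and 5 of 13 microglial markers below it. The SD of the presynaptic genes' deviations in that replicate was 0.60, at the 98.85th percentile, against a median of 0.32 in random lists. It does not decide the question, since genes that other cells also express would be lower by less. That reason does not cover the 9 of 25 genes above their mean in replicate 1, Snap25 and Dnm1 among them. Loss of signal away from the 3′ end cannot be told apart for this list, because 3 genes (Dnm1, Napb and Vamp2) have 2 probe sets above background, and the dimmer was lower in 3 of 3, by a mean of -0.94 (one-sided exact sign-flip test, p = 0.125, the smallest that 3 genes allow).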
